A study of Mus musculus with 10 samples.

How the data were processed

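RNA was measured in mammary tumours of 10 female FVB/N mice, 5 of each genotype. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy Mini kit and libraries were made with the NEBNext Ultra II kit. Per the submitters' processing notes, Trimmomatic, STAR, HTSeq, edgeR and limma were used with the GRCm38 (mm10) genome, with no version given. The annotation release, the strand setting of the counting and the use of multi-mapping reads are not given in the sources used here, so genes that overlap others or have near-identical copies are reported as uncertain. The deposited table covers all 10 libraries and 26063 genes. It gives raw counts per gene and library, which the tests below use. It also gives the authors' normalized counts, a signal that equals the counts divided by 1 factor per library, their means per group, and the authors' FPKM values, which were used only to check how the table was made. The authors' deposited log2 fold changes and p-values describe 16IC over EIC, with an adjusted p of 1 where no p is given (157 genes). The tool behind them is not given in the sources used here, and DESeq2 run on the counts gave the same size factors and the same 356 calls. Across tested genes, which are not independent replicates, the authors' deposited log2 fold changes had a Pearson r of 0.99997 with those of edgeR. No per-sample column was left out.

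Gene identifiers, symbols and positions are those of the table. Of its 26063 identifiers, 26029 are in GENCODE mouse release 21, 25291 (97.0%) with the same chromosome, start and end, and overlaps between genes were taken from that release. Where 1 symbol stands for several identifiers (11 symbols), the lists use the one with the most counts. Groups come from the genotype labels, and the numbers of the tumours follow the order of the samples and pair nothing, so no block was fitted. No batch or date is given in the labels. Libraries of a group were compared for duplicates, and the closest pair, 16IC 2 and 16IC 5, still differed far beyond sampling noise (chi-square per degree of freedom 26.3, Spearman rho 0.987 across genes).

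Depth was 14813940 to 16947400 counts per library, on average 16430717 ± 489955 in EIC and 16024199 ± 1004063 in 16IC (SD, n = 5). The share of mitochondrial counts was 0.549% to 1.41%, and the 10 most counted genes took 5.22% to 10.4% of the counts, most of all Csn3, Spp1, Igfbp5 or Eef1a1. After edgeR's filterByExpr (minimum count 10) 14915 genes holding 99.8% of the counts were tested, and 11148 were not. A gene's biological coefficient of variation was 33.6% at the median, so the spread between tumours, not counting error, limits the precision of most values.

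Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood fit with the robust option, genotype as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were derived from the F statistic and 95% intervals from the same fit. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over 30 lists, and again with an estimated correlation, with fry and with an exact permutation test of the list's mean score. Fry's test of movement in 1 direction passed 0 lists (smallest adjusted p 0.166), its test of movement in either direction 5 (ERBB receptors and ligands, immune checkpoints, luminal epithelium, unfolded protein response, immediate-early and heat shock), and the exact permutation test of scores 0 after adjustment (smallest adjusted p 0.119). Permutation tests of single values are exact, two-sided and run over all 252 arrangements, so their smallest possible p is 0.00794. The scores of skin keratinocytes and of immediate-early and heat shock genes reached it before adjustment. Over 30 lists, adjustment can pass a list only if several lists have a p at or near this value. That 0 lists passed this test therefore says little. P-values of single genes, of fry and of the permutation tests measure the spread between tumours of different animals. Camera's p-values compare the genes of a list with all other genes. With the preset correlation of 0.01 they largely leave out how genes of a list vary together between tumours. Estimated from the data, that correlation ran from -0.00836 (ENPP1 and nucleotide list) to 0.917 (skeletal muscle). The comparison, tests, lists, rule for named genes and most alternatives were chosen before the data were examined.

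The rule for named genes took Enpp1 and Erbb2, then the genes with the largest changes among edgeR's calls, and from the lists the members past the threshold or, in lists past camera without such a member, the 2 with the smallest p. Since edgeR called no gene, the second part took none. Genes called by DESeq2, the 6 largest changes in each direction among its calls (mean log2 CPM of at least 1, no overlap, no predicted-gene name), list members it called, the 6 genes sharing the smallest edgeR adjusted p, and the genes passing with 1 tumour left out were named after the data were seen. Of the genes taken in this way, 1 is not reported here. A symbol that the rule does not give, such as Cd274, Egr2 or S100a9, was likewise chosen after its values were seen. Apobr is overlapped by Cln3 on the opposite strand over 21.0% of its length, Glipr1 by Krr1 over 17.4%, Mb by Apol6 over 16.9% and Enho by an antisense gene over 43.4%, and H2 and heat shock genes have close paralogs, so these are uncertain.

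The procedure was tested on simulated counts for the comparison of 16IC with EIC, drawn for the 14915 tested genes in 3 simulations. edgeR recovered 20.0%, 72.0%, 84.0% and 94.7% of genes changed 2, 4, 8 and 16-fold, with 18 false calls among 424 (4.25%). DESeq2 1.42.0 recovered 37.3%, 80.7%, 95.3% and 98.7%, with 146 false calls among 614 (23.8%). Camera called 0 of 60 unchanged and 3 of 3 changed lists in that simulation, where genes vary independently, so it does not show how often camera calls lists of genes that vary together. Over the other splits of the real tumours the median was 10 lists.

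Alternatives were median-of-ratios scaling, scaling by total count alone, no filter on low counts, a filter of at least 1 CPM in 5 libraries, DESeq2, limma voom with and without quality weights, a 2-fold minimum, lists without shared genes, and leaving out each tumour in turn. After the data were seen, edgeR's likelihood-ratio and exact tests, a fit without the robust option, a surrogate variable (sva 3.50.0) or the first principal component as a covariate, and DESeq2 without each tumour were added. An adjusted p that DESeq2 does not give (9225 genes) was left as missing.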

Results

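Mammary tumours from 10 female FVB/N mice were profiled by bulk RNA sequencing, 5 from mice of the genotype EIC/WT (called EIC here) and 5 from mice of the genotype 16IC/WT (called 16IC). All mice received doxycycline at 2 mg/ml, and the tumours were taken at end point and frozen. The labels do not spell out the names EIC and 16IC. The series title names a HER2 variant, ENPP1 and an immune cold microenvironment. The comparison asks how the transcriptomes of the tumour genotypes differ, with Enpp1 and immune genes in view. Each tumour carries its own animal name, and the number after a group's name only tells its tumours apart. Total counts per library ran from 14813940 (16IC 4) to 16947400 (EIC 5) and did not separate the groups (exact permutation p = 0.405). More genes had at least 1 count in EIC, 20932 ± 757 (SD, n = 5), than in 16IC, 19814 ± 507 (exact permutation p = 0.0476). That p was not adjusted for the other library measures compared. Below, levels are CPM (TMM-scaled) as mean ± SD over the 5 tumours of a group. Differences are log2 of 16IC over EIC, and positions are on GRCm38.

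Enpp1, which encodes an ectoenzyme that hydrolyses extracellular nucleotides, was not separated between the genotypes. Its level was 254 ± 187 CPM in EIC and 160 ± 32.2 CPM in 16IC (n = 5 each), a log2 difference of -0.67 with an SE of 0.45 and a 95% interval from -1.67 to 0.32. The gene (ENSMUSG00000037370) lies on the minus strand of chromosome 10 from 24637914 to 24712159. The adjusted p was 0.521 by edgeR's quasi-likelihood test, and the exact permutation p was 0.516. In the authors' deposited table the log2 fold change of Enpp1 is -0.67 and its adjusted p 0.492. The tumour EIC 2 held the highest Enpp1 level, and without it the log2 difference was -0.17. Erbb2, the mouse gene of the receptor HER2 (ENSMUSG00000062312, plus strand of chromosome 11, 98412470 to 98437716), stood at 127 ± 22.2 CPM in EIC and 128 ± 11.8 CPM in 16IC, with a log2 difference of 0.01, an SE of 0.14 and a 95% interval from -0.30 to 0.32 (adjusted p = 0.991, edgeR). Whether these levels include reads of an introduced HER2 sequence was not tested, so they do not check the genotype labels. The sign of the Erbb2 difference turned negative when libraries were scaled by total count alone (-0.0447).

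Of the other genes of extracellular nucleotide handling, DESeq2 called 4 and edgeR none over all genes tested. Nt5e, the ectoenzyme CD73 that makes adenosine from AMP, was lower in 16IC (90.8 ± 67.7 CPM in EIC, 13.7 ± 4.11 CPM in 16IC, log2 difference -2.73 with SE 0.58). Ada, adenosine deaminase, had 6.90 ± 3.84 CPM in EIC and 42.7 ± 46.2 CPM in 16IC (2.63, SE 0.78). Entpd2, an ectonucleotidase, had 5.37 ± 1.36 and 14.0 ± 6.57 CPM (1.38, SE 0.35). The adenosine receptor gene Adora1 had 17.8 ± 16.4 and 101.9 ± 76.8 CPM (2.52, SE 0.88). Adjusted over all genes tested, edgeR's p was 0.249 for Nt5e, 0.288 for Ada, 0.255 for Entpd2 and 0.305 for Adora1, whereas DESeq2 gave 2.51e-04, 0.0164, 0.0164 and 0.0499. These 4 genes were singled out after their values were seen. Entpd2 is uncertain because Npdc1 overlaps 36.2% of it on the same strand. Of the 22 tested genes of the list on ENPP1, nucleotide and adenosine handling and STING, 12 were higher and 10 lower in 16IC (10 higher when scaled by total count). Of these, 2 passed edgeR's test adjusted over the list alone, Nt5e and Entpd2. The list as a whole did not pass camera (mean log2 difference 0.15, adjusted p = 0.693). The DESeq2 call of Nt5e was made in all 10 fits with 1 tumour left out. That of Ada was lost without EIC 4, EIC 5, 16IC 1 or 16IC 4 (highest adjusted p 0.158). Those of Entpd2 and Adora1 without any of EIC 1, EIC 4, EIC 5, 16IC 1, 16IC 3 and 16IC 4 (highest 0.0857 and 0.205).

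Among the ERBB receptors and ligands, Erbb3 lay near 0 (log2 difference 0.04), Egfr was somewhat higher in 16IC (0.49, edgeR adjusted p = 0.496), and some ligands were lower. Hbegf, a ligand of EGFR, had 44.2 ± 20.1 CPM in EIC and 11.8 ± 4.36 CPM in 16IC, a log2 difference of -1.91 (SE 0.36), with every 16IC tumour below every EIC tumour. Ereg, another EGFR ligand, had 1.94 ± 1.18 and 0.244 ± 0.248 CPM (-2.93, SE 0.78). Both were the list's only calls by edgeR adjusted over the list alone and by DESeq2 over all genes (adjusted p = 2.50e-04 and 0.00968), and both were named after their values were seen. Over all genes tested edgeR's adjusted p was 0.186 for Hbegf and 0.261 for Ereg, and the DESeq2 call of Ereg was lost without EIC 1 or EIC 5 (highest adjusted p 0.0598). Of the 16 tested members, 8 were higher and 8 lower (6 higher when scaled by total count). The list did not pass camera (mean -0.49, adjusted p = 0.274), but it passed fry's test of movement in either direction (adjusted p = 0.0325). EIC 3 stood apart in this list, and without it the mean was -0.12. Feedback genes of receptor tyrosine kinase and MAPK signalling were divided, 11 higher and 8 lower of 19, with a mean log2 difference of 0.01 and a camera adjusted p of 0.474.

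Across all 14915 genes tested, the genotypes were separated weakly at the level of single genes. edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05, with 1958 genes at an unadjusted p under 0.05 (1020 higher and 938 lower in 16IC) against 745.75 expected by chance. DESeq2, run on all 26063 genes without that filter, called 356 genes, 142 higher and 214 lower, and the same 356 pass in the authors' deposited table. Of these calls, 305 were among the genes tested by edgeR and 51 lay below its count filter. Of the 51, 12 were called in all 10 fits with 1 tumour left out. The smallest edgeR adjusted p, 0.0947, was shared by 6 genes, all lower in 16IC and without overlap between the groups: Actg2, Glipr1, Apobr, Ramp3, Plekhb2 and C130071C03Rik. Actg2, a smooth muscle actin, had 6.82 ± 2.68 CPM in EIC and 0.810 ± 0.373 CPM in 16IC (log2 difference -3.07, SE 0.41). Glipr1 had 33.7 ± 22.96 and 2.03 ± 0.884 CPM (DESeq2's adjusted p = 9.08e-11), and Apobr, an apolipoprotein B receptor, 71.8 ± 60.6 and 5.14 ± 1.75 CPM (DESeq2's adjusted p = 1.29e-10). Ramp3, an accessory protein of calcitonin-family receptors, had 5.14 ± 1.72 and 1.24 ± 0.117 CPM, and Plekhb2 59.4 ± 5.49 and 34.7 ± 2.80 CPM. The non-coding gene C130071C03Rik had 7.74 ± 6.24 CPM in EIC and 0.0362 ± 0.0542 CPM in 16IC.

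The largest gains among DESeq2's calls without overlap were in Csn1s2b, a casein gene (0.731 ± 0.974 CPM in EIC, 91.9 ± 153 CPM in 16IC, log2 difference 6.95, and 5.12 to 8.20 with 1 tumour left out), Sgsm1 (3.85), Car8, a carbonic anhydrase related protein (3.46), Tmem56 (8.43 ± 2.73 and 45.1 ± 21.4 CPM, 2.42), Enho (2.29) and Insl6 (2.10). The level of Csn1s2b was 357.4 CPM in 16IC 1, 90.9 CPM in 16IC 4 and 2.93 to 4.58 CPM in the other 16IC tumours. Large losses were in the transcription factor gene Dmrta2 (28.0 ± 17.0 and 1.10 ± 1.02 CPM, -4.64), Glipr1 (-4.05), Apobr (-3.80), Actg2 (-3.07) and the protease gene Klk8 (-2.96). These genes were taken by the rule for named genes applied to DESeq2's calls after the data were seen, since edgeR made no call. DESeq2 called each of them in every fit with 1 tumour left out that gave it an adjusted p, except Car8 without 16IC 4 (0.0567). Groups without overlap were found for 385 genes, 2.58% of those tested, where chance gives 0.794% on average. Genes vary together between tumours, and this count was not made for other splits of the tumours. It therefore does not show that chance is exceeded. The number of DESeq2 calls moved with single tumours, to 217 without EIC 1, 839 without EIC 2, 203 without EIC 4, 549 without 16IC 2, 226 without 16IC 3, 178 without 16IC 4 and 579 without 16IC 5. With edgeR, 1 gene passed without EIC 1 (Slc22a18, log2 difference 2.46, adjusted p = 0.0310) and 2 without EIC 2 (Adamts4, -2.76, and C130071C03Rik, each with adjusted p = 0.0254), all named after their values were seen.

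**Figure D1:**
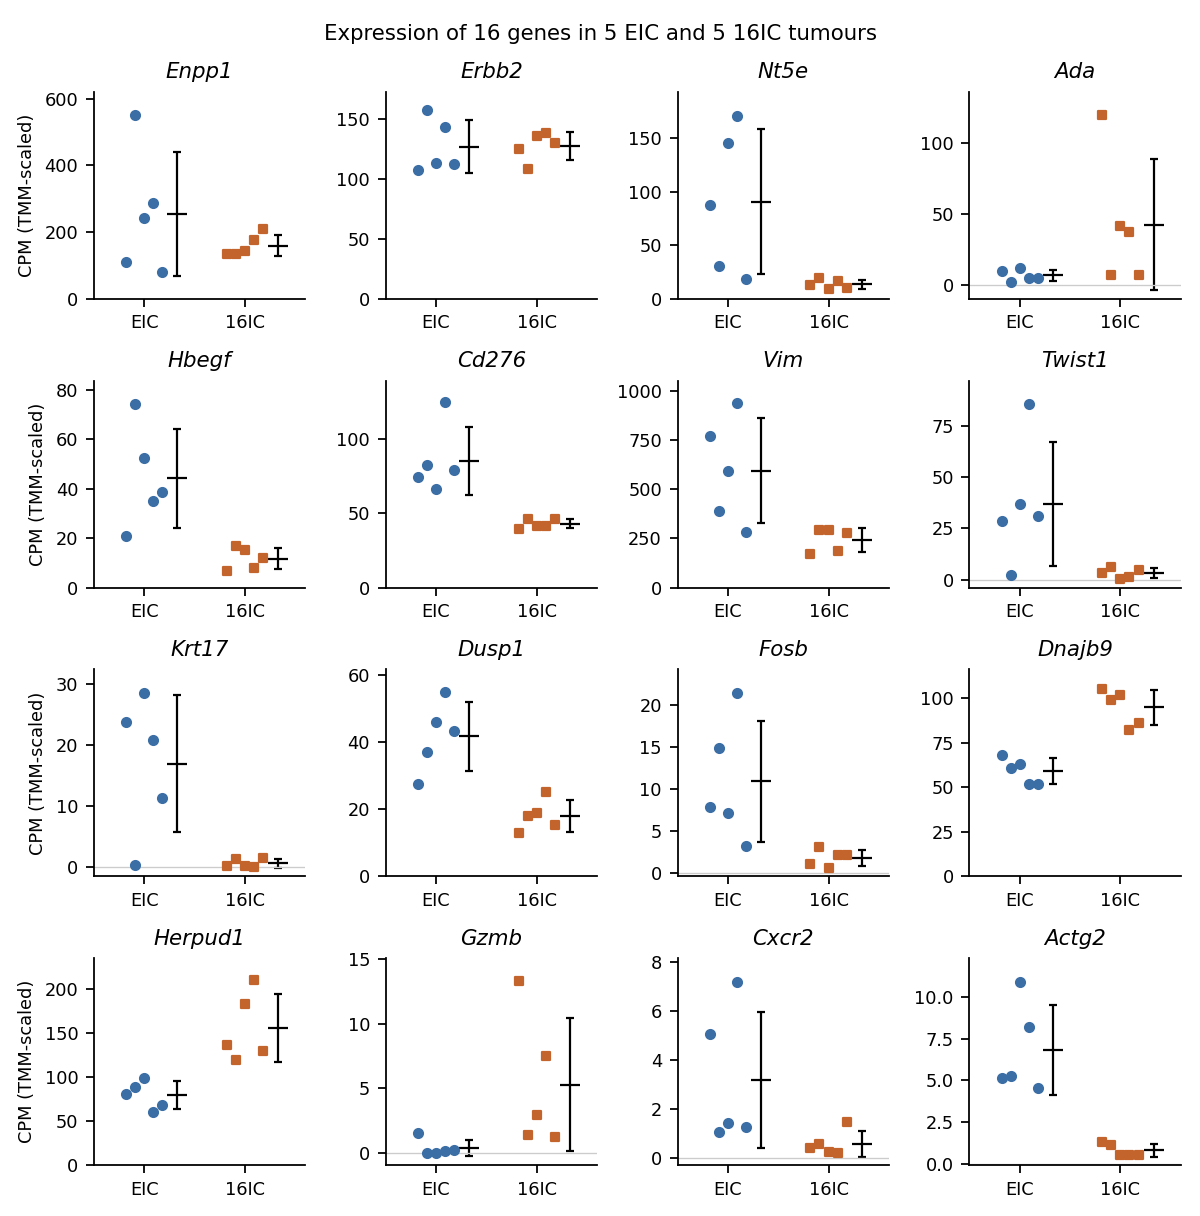
Expression of 16 genes in CPM scaled by TMM (linear axes), with a circle for each of the 5 EIC tumours, a square for each of the 5 16IC tumours, and the group mean with 1 SD as a bar. For Enpp1 the groups overlap (254 ± 187 and 160 ± 32.2 CPM), while for Cd276, Hbegf, Dusp1, Fosb, Dnajb9, Herpud1 and Actg2 no 16IC tumour lies among the EIC tumours.

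Immune lists pointed in different directions. Of the 30 gene lists fixed beforehand, 17 passed camera with its preset correlation (4 higher and 13 lower in 16IC). With the same lists, 0 passed with a correlation estimated from the data, where the smallest adjusted p was 0.705 and 1 list had an unadjusted p under 0.05. No member of any list passed edgeR's test over all genes tested. Genes of MHC class II presentation were higher for 9 of 10 tested members, with a mean log2 difference of 0.82 (camera adjusted p = 0.00879, and 0.705 with an estimated correlation). Among them were the peptide-loading genes H2-DMb2 (10.4 ± 4.53 and 25.6 ± 12.2 CPM, log2 difference 1.31) and H2-DMb1 (10.5 ± 4.62 and 21.7 ± 10.5 CPM, 1.04). Without 16IC 1 the class II mean was 0.43. MHC class I presentation was higher for 19 of 19 members (18 when scaled by total count), by a mean of 0.56 (camera adjusted p = 0.0240, and 0.705 with an estimated correlation). Examples were Pdia3, a chaperone of peptide loading (1268 ± 197 and 1702 ± 272 CPM), and H2-T23 (14.4 ± 6.01 and 34.6 ± 23.2 CPM), which lies within an antisense gene and is uncertain. The class I call was lost without EIC 2, EIC 3, 16IC 1 or 16IC 4 (highest adjusted p 0.548, without 16IC 1, where the mean was -0.03), with voom and quality weights (0.284) and with the first principal component as a covariate (0.0597). No member of either list passed adjusted over the list alone. Interferon-stimulated genes did not pass (adjusted p = 0.0503), with 20 higher and 16 lower of 36 (15 higher when scaled by total count) and a mean of 0.09, which ran from -0.56 without 16IC 1 to 0.53 without EIC 4. The interferon score was 7.22 in 16IC 1, as mean log2 CPM, and 4.96 to 5.56 in the other 4 16IC tumours. Ifi27, an interferon-induced mitochondrial protein named after its values were seen, had 149 ± 52.8 CPM in EIC and 295 ± 45.1 CPM in 16IC without overlap (edgeR adjusted p = 0.249). DESeq2 called it (adjusted p = 0.0209), but not without EIC 3, EIC 4, 16IC 1, 16IC 3 or 16IC 4 (highest 0.0878).

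Lymphocyte transcripts were few in both genotypes. The 25 genes of the T cell list summed to 64.2 ± 31.2 CPM in EIC and 36.8 ± 14.6 CPM in 16IC (exact permutation p = 0.135). Most of these sums came from Thy1 (28.1 and 18.5 CPM) and Tcf7 (17.5 and 5.29 CPM), which other cells also express, while Cd3d, Cd3e and Cd3g each lay under 1 CPM. Of the list, only 6 were abundant enough to test, 1 higher and 5 lower (mean -0.52, camera adjusted p = 0.426). With 1 tumour left out the mean ran from -0.84 (without EIC 2) to -0.21 (without EIC 1). Genes of B and plasma cells summed to 45.8 ± 65.1 and 15.1 ± 9.52 CPM (exact permutation p = 0.397), with all 6 tested members lower (mean -1.20, camera adjusted p = 0.299). EIC 1 alone held 160.4 CPM, and the mean was -0.29 without it and -1.85 without 16IC 5. The list of NK and cytotoxic cells summed to 9.68 ± 9.85 and 20.6 ± 16.5 CPM (exact permutation p = 0.135), and 5 of its 6 tested members were higher (mean 0.997, camera adjusted p = 0.0391, and 0.705 with an estimated correlation). Its call was lost without EIC 2, EIC 3 or 16IC 1 (highest adjusted p 0.257), with voom and quality weights (0.383) and with the filter of at least 1 CPM in 5 libraries (0.0551). The mean was 0.45 without 16IC 1 and 1.75 without EIC 1. Gzmb, the cytotoxic granule protease granzyme B, was its only member past the test adjusted over the list alone, with 0.411 ± 0.652 CPM in EIC and 5.30 ± 5.12 CPM in 16IC (log2 difference 3.65, SE 1.09, edgeR adjusted p = 0.288). DESeq2 called Gzmb (adjusted p = 0.0139), but not without EIC 4, EIC 5, 16IC 1 or 16IC 4 (highest 0.125). Il2rb, an interleukin receptor chain of NK and T cells, had 2.02 ± 2.09 and 3.78 ± 3.92 CPM. Over 9 immune lists the summed levels gave no exact permutation p under 0.05 after adjustment (smallest adjusted p 0.405).

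The neutrophil, macrophage and chemokine lists passed camera with the preset correlation, as lower in 16IC. All 9 tested neutrophil genes were lower, by a mean of -1.58 (camera adjusted p = 2.76e-04, and 0.705 with an estimated correlation). Adjusted over the list alone, 4 passed: S100a8, S100a9, Mmp9 and Cxcr2. Cxcr2, a chemokine receptor of neutrophils, had 3.20 ± 2.77 CPM in EIC and 0.588 ± 0.515 CPM in 16IC (log2 difference -2.42). Mmp9, a matrix protease, had 8.55 ± 7.79 and 1.76 ± 1.10 CPM (-2.27). S100a8, a calcium-binding protein of neutrophils named after its values were seen, had 14.6 ± 12.96 and 2.68 ± 1.78 CPM (-2.44). DESeq2's calls of these 3 (adjusted p = 0.0341, 0.0301 and 0.0258) were all lost without EIC 1, EIC 4, 16IC 1, 16IC 3 or 16IC 4, and that of Cxcr2 also without 16IC 2 (highest 0.195, 0.213 and 0.178). Summed over the neutrophil list, which is dominated by Ltf, a gene also of the milk list, the levels were 1924 ± 3356 and 960 ± 834 CPM (exact permutation p = 0.992). Genes of macrophages and monocytes were lower for 19 of 23 members (20 of 23 when scaled by total count), by a mean of -0.35 (camera adjusted p = 0.00879, and 0.705 with an estimated correlation). They summed to 1454 ± 574 and 1227 ± 728 CPM (exact permutation p = 0.381). Fcgr1, an Fc receptor, had 13.2 ± 5.77 and 8.55 ± 2.43 CPM, and Itgam, which shares 99.9% of its length with another annotated gene on the same strand and is uncertain, 6.32 ± 2.01 and 3.22 ± 2.14 CPM. The macrophage call was lost without EIC 1 (adjusted p = 0.0737) and with a surrogate variable as a covariate (0.961), and its direction turned with the first principal component as a covariate (mean 0.06). Chemokines were lower for 17 of 21 members (mean -0.55, camera adjusted p = 0.0258, and 0.705 with an estimated correlation). Among them were Cxcl14 (162 ± 97.496 and 51.0 ± 34.8 CPM) and Cxcl5 (2.53 ± 2.23 and 0.566 ± 0.693 CPM). That call was lost without EIC 1, EIC 4 or 16IC 3 (highest adjusted p 0.124), and with a surrogate variable (0.842) or the first principal component (0.660) as a covariate. The macrophage mean was -0.21 without EIC 1 and -0.57 without 16IC 5, and the chemokine mean -0.35 without EIC 4. No member of the macrophage or chemokine lists passed adjusted over the list alone.

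Dendritic cell genes did not pass camera (2 higher and 9 lower of 11, mean -0.26, adjusted p = 0.292), with a mean from -0.48 (without 16IC 5) to -0.06 (without EIC 4). Their only member past the test adjusted over the list alone was Fscn1, an actin-bundling protein that is not restricted to dendritic cells (134 ± 74.4 and 33.9 ± 9.49 CPM, log2 difference -1.98). Immune checkpoint genes narrowly missed camera's threshold (5 higher and 14 lower of 19, mean -0.31, and -0.16 without EIC 1, adjusted p = 0.0507). As a list they passed fry's test of movement in either direction (adjusted p = 0.0233). Cd276, the B7-H3 checkpoint ligand (ENSMUSG00000035914, minus strand of chromosome 9, 58524298 to 58555437), was the only member past the test adjusted over the list alone, at 85.3 ± 22.7 CPM in EIC and 42.9 ± 3.15 CPM in 16IC (-0.99, SE 0.17) with no overlap between the groups. Its adjusted p over all genes was 0.154 by edgeR and 3.13e-04 by DESeq2, which called Cd276 and Fscn1 in all 10 fits with 1 tumour left out. Fscn1 and Cd276 were named after their values were seen. The ligand gene Cd274 (PD-L1) had 4.70 ± 2.82 CPM in EIC and 12.3 ± 16.02 CPM in 16IC, with an edgeR adjusted p of 0.449, and 1 tumour held 565 of its 898 counts in 16IC.

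The lists of mesenchymal, basal and fibroblast genes passed camera with the preset correlation, as lower in 16IC. Every one of the 16 tested genes of epithelial-mesenchymal transition was lower, by a mean of -1.14 (camera adjusted p = 4.02e-06, and 0.705 with an estimated correlation). Adjusted over the list alone, 7 passed. Vim, the intermediate filament vimentin, had 593 ± 267 CPM in EIC and 244 ± 61.3 CPM in 16IC (log2 difference -1.28, SE 0.33). The transcription factor gene Twist1 had 37.0 ± 30.5 and 3.15 ± 2.45 CPM (-3.55, SE 0.91). DESeq2 called both (adjusted p = 0.0168 and 0.00160), Twist1 in all 10 fits with 1 tumour left out. The call of Vim was lost without EIC 1, EIC 4, 16IC 1 or 16IC 4 (highest adjusted p 0.0914). Basal and myoepithelial genes were lower for 13 of 14 members (mean -1.41, camera adjusted p = 0.00107, and 0.705 with an estimated correlation). The basal keratin Krt17 (17.0 ± 11.2 and 0.656 ± 0.733 CPM, -4.65, SE 1.15) was the only one past the test adjusted over the list alone, and Krt14 (142 ± 194 and 4.09 ± 5.82 CPM, -5.10, SE 1.80) had an edgeR adjusted p of 0.307. The basal call was lost with the first principal component as a covariate (adjusted p = 0.200). Genes of fibroblasts and matrix were lower for 19 of 20 members (20 when scaled by total count), by a mean of -0.68 (camera adjusted p = 2.55e-04, and 0.705 with an estimated correlation). None passed the test adjusted over the list alone. Examples were Fn1, fibronectin (664 ± 450 and 185 ± 105 CPM), and Pdgfrb, a receptor of pericytes and fibroblasts (48.8 ± 24.8 and 28.3 ± 9.20 CPM). That call was lost with the first principal component (adjusted p = 0.579) or a surrogate variable (0.0735) as a covariate, and the mean was -0.39 without EIC 1 and -0.42 without 16IC 3.

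Lists of other tissues around a mammary tumour also passed camera with the preset correlation, as lower in 16IC. Skeletal muscle genes were lower for all 15 tested members, by a mean of -2.83, and by -4.61 without 16IC 1 and -1.84 without EIC 2 (camera adjusted p = 1.26e-05, and 0.705 with an estimated correlation), but with a wide spread between tumours of 1 genotype. Eno3, muscle enolase, had 34.6 ± 35.1 and 7.04 ± 5.02 CPM, and Mb, myoglobin, 14.1 ± 8.09 and 5.47 ± 2.74 CPM. Relative to the mean of all 10 tumours, the muscle score was 4.49 in EIC 2 and -3.24 in EIC 3 on the log2 scale, and it ran from -4.07 (16IC 3) to 1.97 (16IC 1) in 16IC. Adipocyte genes were lower for 13 of 15 members (mean -0.54, camera adjusted p = 0.00989, and 0.705 with an estimated correlation). Examples were Lpl, lipoprotein lipase (44.6 ± 19.3 and 30.3 ± 16.4 CPM), and Pck1 (21.9 ± 17.2 and 6.86 ± 10.2 CPM). Endothelial genes were lower for 11 of 16 (14 when scaled by total count), by a mean of -0.27 (camera adjusted p = 0.0373, and 0.705 with an estimated correlation), as were the VEGF receptor gene Flt1 (37.2 ± 14.9 and 21.5 ± 4.46 CPM) and Cldn5, a tight junction gene (9.93 ± 3.61 and 5.75 ± 2.29 CPM). All 3 tested genes of skin keratinocytes were lower (mean -1.51, camera adjusted p = 0.0391, and 0.705 with an estimated correlation). Dmkn (9.68 ± 10.1 and 1.17 ± 0.308 CPM) and Sbsn (6.66 ± 3.11 and 2.83 ± 0.525 CPM) passed adjusted over the list alone. These genes lie close together on chromosome 7 (30763756 to 30781063 and 30751471 to 30756134). The third tested gene, the keratin Krt10, had a log2 difference of -0.25 (edgeR adjusted p = 0.797). Sbsn shares 99.8% of its length with another annotated gene on its strand and is uncertain. The adipocyte call was lost without EIC 1 or 16IC 3 (highest adjusted p 0.0931), with DESeq2 (0.425), a surrogate variable (0.787) or the first principal component (0.458). The adipocyte mean was -0.25 without EIC 1, -0.26 without 16IC 3, -0.33 without 16IC 4, -0.81 without EIC 3, -0.83 without 16IC 5 and -1.22 without 16IC 2. The endothelial call was lost without EIC 1, EIC 3, EIC 4 or 16IC 3 (0.774), with DESeq2 (0.104), without the filter on low counts (0.0723), and with a surrogate variable (0.851) or the first principal component (0.822), and its mean was -0.08 without 16IC 3. The keratinocyte call was lost without EIC 1, 16IC 2, 16IC 4 or 16IC 5 (0.134), with voom (0.0637, and 0.0795 with quality weights), and with a surrogate variable (0.0735) or the first principal component (0.114).

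Luminal epithelial genes as a list did not pass camera (11 higher and 10 lower of 21, camera adjusted p = 0.938). Fry's test of movement in either direction passed the list (adjusted p = 0.0325). The list's mean (-0.05) and median (0.09) differ in sign, and camera's direction is up. Its 2 members past the test adjusted over the list alone were both higher in 16IC and were named after their values were seen. Gata3, a luminal transcription factor, had 106 ± 21.3 CPM in EIC and 193 ± 52.1 CPM in 16IC (log2 difference 0.86, SE 0.20) with no overlap between the groups. It is uncertain, since another gene overlaps 19.7% of its length on the same strand. Spdef, an epithelial transcription factor, had 0.979 ± 1.21 and 21.7 ± 24.5 CPM (4.46, SE 1.21). DESeq2 called both (adjusted p = 0.0206 and 0.00103), Spdef in all 10 fits with 1 tumour left out and Gata3 not without EIC 4, EIC 5, 16IC 1 or 16IC 3 (highest adjusted p 0.0825). The groups overlapped for Spdef, which stood at 1.37 CPM in 16IC 2 and 1.35 CPM in 16IC 5, against 0.125 to 3.12 CPM in EIC. Genes of milk proteins and secretion were divided (8 higher and 9 lower of 17, mean 0.42, median -0.16, camera direction up, adjusted p = 0.208). With 1 tumour left out their mean ran from -0.50 (without 16IC 1) to 1.07. Csn1s2b was the only one of them past the test adjusted over the list alone.

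**Figure D2:**
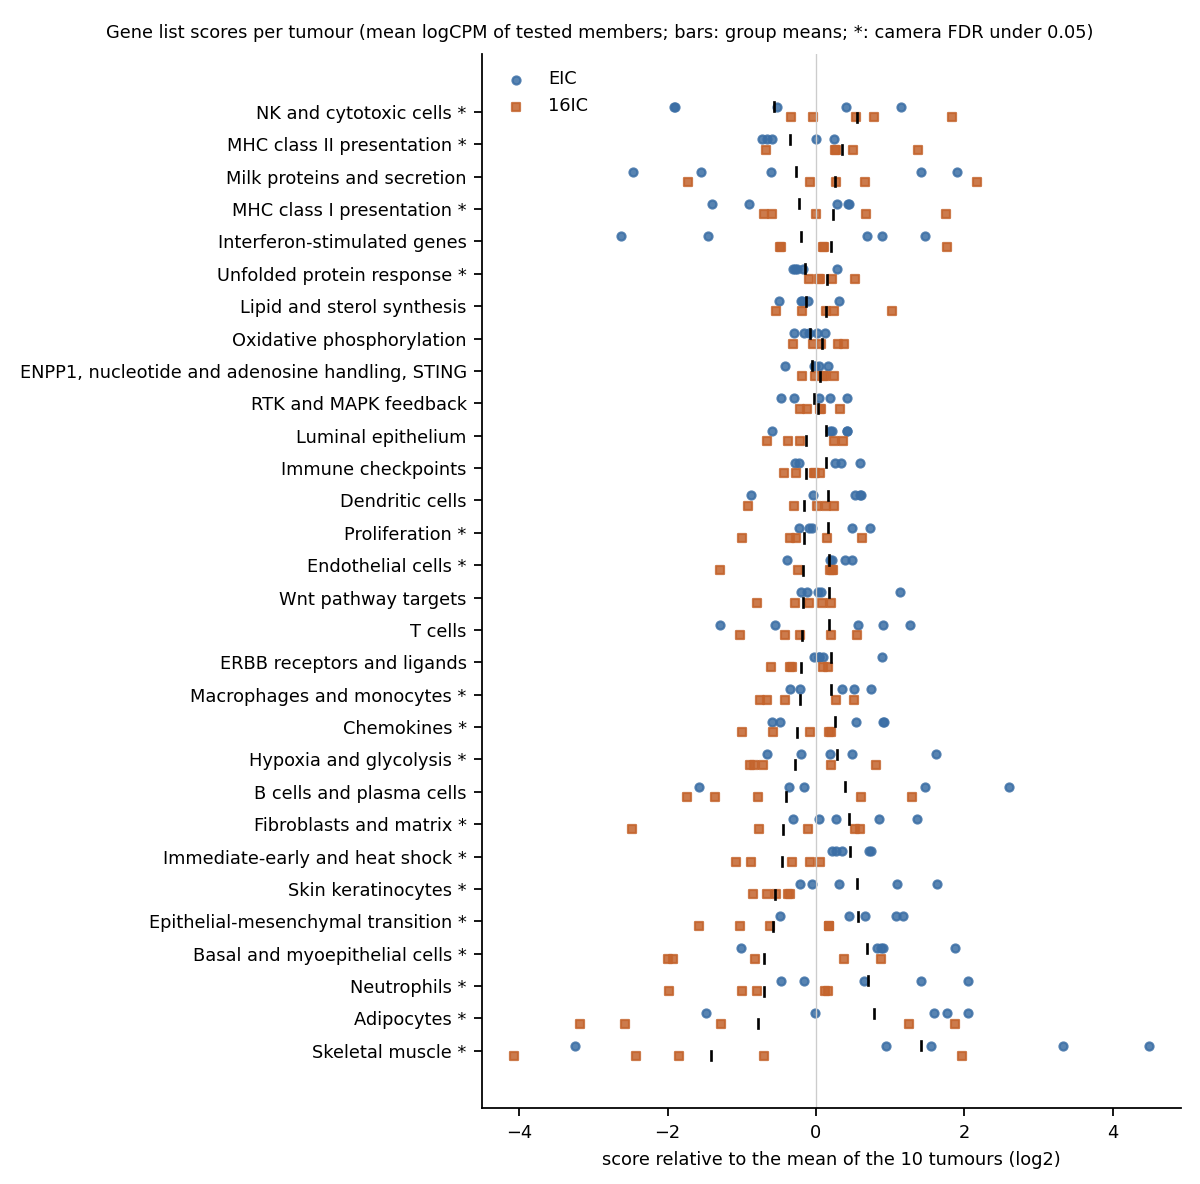
Score of each of the 30 gene lists in each tumour, as the mean log2 CPM of its tested members relative to the mean of the 10 tumours (x axis, log2), with circles for EIC, squares for 16IC, vertical bars for group means and asterisks for the 17 lists past camera with the preset correlation. Skeletal muscle spans the widest range, and the interferon score of 16IC 1 lies apart from the other 16IC tumours.

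Lists of stress responses pointed in opposite directions. The unfolded protein response was higher in 16IC for 16 of 22 members (15 when scaled by total count), by a mean of 0.30 (camera adjusted p = 0.00734, and 0.705 with an estimated correlation). Dnajb9, a co-chaperone of the endoplasmic reticulum (ENSMUSG00000014905, minus strand of chromosome 12, 44205559 to 44210326), had 59.2 ± 7.09 CPM in EIC and 94.8 ± 9.98 CPM in 16IC, a log2 difference of 0.68 (SE 0.13). Herpud1, of endoplasmic reticulum associated degradation (ENSMUSG00000031770, plus strand of chromosome 8, 94386438 to 94395377), had 79.7 ± 15.7 and 156 ± 38.9 CPM (0.97, SE 0.20). These were the 2 members past the test adjusted over the list alone. The list's call was lost without 16IC 1 (adjusted p = 0.0591). Immediate-early and heat shock genes were lower for 15 of 16 members (16 when scaled by total count), by a mean of -0.86 (camera adjusted p = 4.02e-06, and 0.705 with an estimated correlation). Adjusted over the list alone, 4 passed: Dusp1, Fosb, Fos and Egr2. Dusp1, a MAPK phosphatase (ENSMUSG00000024190, minus strand of chromosome 17, 26505590 to 26508519), had 41.7 ± 10.2 CPM in EIC and 18.0 ± 4.63 CPM in 16IC (-1.21, SE 0.23). Fosb, an AP-1 transcription factor, had 10.96 ± 7.22 and 1.84 ± 0.968 CPM (-2.57, SE 0.57). In Dnajb9, Herpud1, Dusp1 and Fosb the groups did not overlap, and edgeR's adjusted p over all genes was 0.154, 0.216, 0.154 and 0.249. DESeq2 called all 4 in each of the 10 fits with 1 tumour left out (with all tumours 7.03e-04, 0.00417, 7.03e-04 and 6.93e-04).

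Proliferation genes were lower for 22 of 26 members (23 when scaled by total count), by a mean of -0.26 (camera adjusted p = 0.0102, and 0.705 with an estimated correlation). Examples were Top2a (125 ± 45.8 and 80.6 ± 24.9 CPM) and Mki67 (127 ± 74.4 and 74.6 ± 26.4 CPM). None passed the test adjusted over the list alone. Genes of hypoxia and glycolysis were lower for 15 of 19 members (16 when scaled by total count). Their mean was -0.73 and their median -0.30 (camera adjusted p = 0.0150, and 0.705 with an estimated correlation). Slc16a3, a lactate transporter, was the only member past the test adjusted over the list alone (35.1 ± 14.2 and 9.87 ± 5.87 CPM, log2 difference -1.83, SE 0.46, edgeR adjusted p = 0.254). DESeq2 called it in all 10 fits with 1 tumour left out (with all tumours adjusted p = 0.0103). P4ha1, a collagen prolyl hydroxylase, had 151 ± 57.9 and 74.9 ± 31.5 CPM. Gapdh (log2 difference -3.22), which enters that mean, is uncertain, since pseudogene copies can share its reads. Its counts ran from 79 to 6828 in EIC and from 65 to 347 in 16IC. The proliferation call was lost without EIC 3, EIC 4 or 16IC 5 (highest adjusted p 0.335) and with DESeq2 (0.0610). The hypoxia call was lost without EIC 3, 16IC 1, 16IC 2 or 16IC 5 (0.305) and with voom and quality weights (0.0612). The proliferation mean was -0.10 without EIC 4, -0.11 without 16IC 5 and -0.50 without 16IC 3, and the hypoxia mean -0.27 without EIC 3. Oxidative phosphorylation (16 higher of 20, 13 when scaled by total count, mean 0.16, 0.07 without 16IC 3 and 0.25 without 16IC 5, adjusted p = 0.0638), lipid and sterol synthesis (15 higher of 20, mean 0.35, and 0.08 without 16IC 1, adjusted p = 0.0764) and Wnt pathway targets (3 higher and 9 lower of 12, mean -0.46, and -0.07 without EIC 1, adjusted p = 0.617) did not pass camera.

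The tumours varied strongly within each genotype. The first principal component of the 1000 most variable genes held 48.9% of the variance and did not separate the genotypes (exact permutation p = 0.167). It placed EIC 1, EIC 4, EIC 5, 16IC 2 and 16IC 5 at 25.8 to 51.9, EIC 3 at -3.67, and EIC 2, 16IC 1, 16IC 3 and 16IC 4 at -60.9 to -35.6. Among the genes with the highest loadings on it were Krt14, Krt19 and the adipocyte genes Adipoq, Plin1 and Cidec. The second component held 15.4% of the variance (exact permutation p = 0.0794) and was led at its high end by skeletal muscle genes such as Acta1, Ckm and Myh4, with EIC 2 highest at 52.9.

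**Figure D3:**
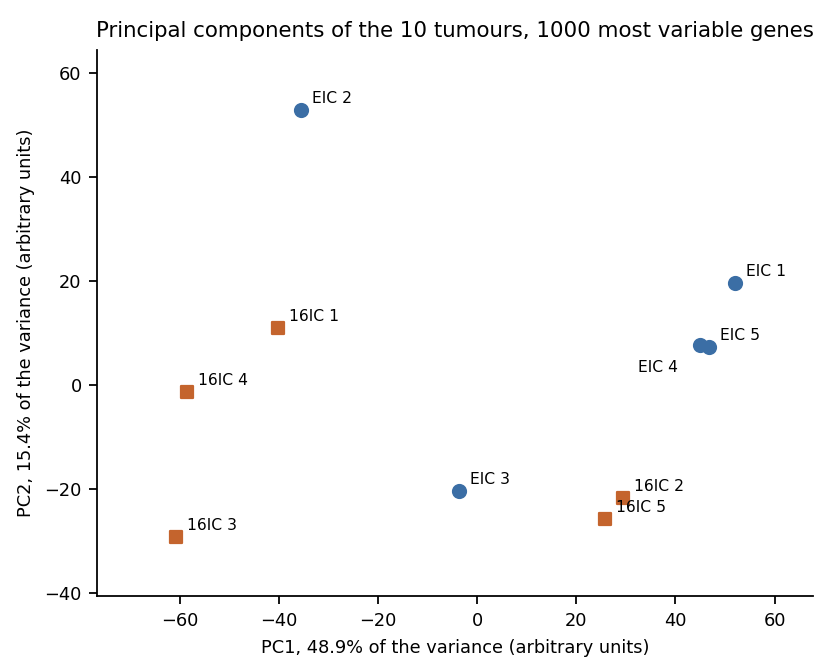
First (x axis, 48.9% of the variance) and second (y axis, 15.4%) principal component of log2 CPM over the 1000 most variable genes, in arbitrary units, with EIC tumours as circles and 16IC tumours as squares. Tumours of both genotypes lie on both sides of the first component.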

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

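The splits of the samples were set in the design for edgeR's gene count, while the splits for the other counts and the tests of outlying tumours, chromosome segments, cell types and muscle were chosen only after the results were seen. In 9 of 204 groups of 5 values (4.41%) the highest or lowest tumour lay far from the other 4, and chance alone sets apart about 1 in 20 groups. Eno3 was 4.004 log2 CPM in 16IC 1 against 2.11 to 2.63 in the other 16IC tumours. Krt17 was -1.06 log2 CPM in EIC 2 against 3.52 to 4.84 in the other EIC tumours. Fscn1 was 4.14 log2 CPM in 16IC 3 against 5.13 to 5.34. As mean log2 CPM of a list, ERBB receptors and ligands stood at 4.33 in EIC 3 against 3.40 to 3.53, and interferon-stimulated genes at 7.22 in 16IC 1 against 4.96 to 5.56. The luminal list stood at 5.96 in EIC 2 against 6.75 to 6.97, the unfolded protein response at 7.30 in EIC 3 against 6.70 to 6.84, and Wnt pathway targets at 3.82 in EIC 1 against 2.48 to 2.75. The mitochondrial share was 1.41% in 16IC 2 against 0.606% to 0.734% in the other 16IC tumours.

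The number of genes that differ between the genotypes could arise by chance. Among 100 splits of the 10 tumours, the genotype split included, 8 gave at least edgeR's 1958 genes at an unadjusted p under 0.05 (highest other split 4865, median of the others 463). At least 17 lists were called in 10 (highest other 22, median 10), and at least DESeq2's 356 genes in 7 (highest other 3786, median 6), so chance cannot be excluded for these 3 counts. For edgeR's 0 calls the splits decide nothing, since all 100 give at least 0 (highest other 2491). The split with 2491 edgeR and 3786 DESeq2 calls sets EIC 1, EIC 4, EIC 5, 16IC 2 and 16IC 5 against the rest, which points to a structure of the samples that cuts across genotype. A call that rests on 1 tumour is lost without it. Of the 356 DESeq2 calls, 113 (31.7%) were made in each of the 10 fits with 1 tumour left out, so these 113 do not rest on 1 tumour alone. The 95% interval of that share (26.9% to 36.9%) treats genes as independent, which they are not. The fits share most of their tumours, so a pattern carried by several tumours is not excluded for these calls. For the other calls, single outlying tumours as the cause stay open. Of the 305 calls among the genes tested by edgeR, 119 had another call within 1 Mb, where random sets of tested genes gave 90 to 130 (mean 109.8). This argues against a segment of 1 chromosome that differs between the lines as the whole cause of these calls. A segment that holds some of the calls would not be seen by this count. The genotype itself stays open beside chance.

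Lists of several other cell types were lower in 16IC together. A smaller share of all other cell types alike predicts that no pair of these lists moves apart. Over all 55 pairs of 11 cell-type lists, the largest t had an exact permutation p of 0.119, for skin keratinocytes against NK and cytotoxic cells (difference -2.23 on the log2 scale), and macrophages against neutrophils had 0.349 (difference 0.98). The NK list alone pointed up in 16IC (mean 0.997) while fibroblast, neutrophil and muscle lists pointed down. With 5 tumours per group, a smaller share of other cells and separate changes in each cell type cannot be told apart here, and a biological difference between the genotypes stays open.

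The skeletal muscle list was lower in 16IC, with its highest level in an EIC tumour and its lowest EIC level below most of 16IC. Muscle tissue in some of the tumour pieces may account for it. The 15 tested members, none of which is in another list, rose and fell together over the 10 tumours. Their median pairwise r was 0.936, where random lists of like expression gave -0.10 to 0.17. Other lists also varied together, with an estimated correlation of 0.883 for interferon-stimulated genes and 0.917 for muscle. The comparison with random lists therefore does not tell muscle tissue from another shared cause. The most abundant members were Acta1 (385 ± 491 CPM in EIC, 49.7 ± 82.2 CPM in 16IC) and Myh4 (139 ± 180 and 9.30 ± 18.4 CPM). Whether tumours of the genotypes take in muscle to different extents was not tested.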

How the results depend on the processing

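The likelihood-ratio and exact tests, the fit without the robust option, both covariates and DESeq2 without each tumour were chosen after the data were seen, and where a value changed the cause was not tested. The count of genes past an adjusted p of 0.05 was 0 under both other scalings, both other filters, voom with and without weights, the fit without the robust option, both covariates and the 2-fold minimum. It was 356 with DESeq2, 167 with the likelihood-ratio test (63 higher, 104 lower), 154 with edgeR's exact test and 0 to 2 with 1 tumour left out. DESeq2's count ran from 178 to 839 with 1 tumour left out, sharing 166 to 318 calls with the fit of all 10. DESeq2 put the median log2 difference of all genes at -0.11, over more low-count genes, against -0.02 with edgeR. The count of lists was 17, 12 to 20 under other settings, 14 to 20 with 1 tumour left out, and 18 without shared genes. It was 0 with an estimated correlation and 0 with fry's test of movement in 1 direction. Fry's test of movement in either direction passed 5. MHC class II presentation, neutrophils, skeletal muscle, epithelial-mesenchymal transition and immediate-early genes passed under all 21 other settings that kept the preset correlation. Enpp1 stayed lower in 16IC and unpassed in each setting, from -0.90 to -0.17 with 1 tumour left out and -0.12 with quality weights.

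Reversed directions, by sign for a gene and by camera's direction for a list, were these, as log2 differences or list means, none of them past the threshold. With the first principal component as a covariate, Erbb2 became -0.105, Lpl 0.0320, T cells 0.386, B and plasma cells 0.256, macrophages 0.0639, dendritic cells 0.114, chemokines 0.00273, endothelial cells 0.0198, oxidative phosphorylation -0.00292 and RTK feedback -0.0920, and camera's direction for adipocytes turned at a mean of -0.0122. With a surrogate variable, Erbb2 became -0.0769, T cells 0.186 and dendritic cells 0.0171, and camera's direction for B and plasma cells turned at a mean of -0.135. With total count alone Erbb2 became -0.0447. With voom and quality weights the interferon list became -0.217 and the luminal list -0.408, and with voom alone the luminal list -0.302. With 1 tumour left out, directions turned within -0.0497 to 0.105 for Erbb2, 0.0919 to 0.212 for the ENPP1 and nucleotide list, -0.556 to 0.527 for interferon-stimulated genes, -0.239 to -0.0123 for the luminal list, -0.0991 to 0.137 for RTK feedback and -0.664 to -0.0703 for Wnt targets. Where such a list mean kept its sign, camera's direction turned. List means that changed sign while camera's direction did not were those of MHC class I (-0.0331) and milk proteins (-0.504) without 16IC 1, the ENPP1 and nucleotide list with a surrogate variable (-0.0248) or the first principal component (-0.0682), the luminal list with the latter (0.0168), RTK feedback with total count alone (-0.0414), a surrogate variable (-0.0736) or without EIC 5, 16IC 2, 16IC 3 or 16IC 5 (-0.0700 to -0.00950), and the interferon list without 16IC 1 (-0.556) or EIC 3 (-0.135). At the depth of 14813940 to 16947400 counts, 6 of 25 T cell and 3 of 13 keratinocyte genes could be tested, and depth as the cause was not tested.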

Other observations

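Transcripts of immune lists varied widely between tumours of 1 genotype. Genes of B and plasma cells summed to 160.4 CPM in EIC 1 and to 8.73 to 37.0 CPM in the other EIC tumours. T cell genes summed to 104.0 CPM in EIC 1, 82.5 in EIC 4, 66.8 in EIC 5, 41.3 in EIC 3 and 26.2 in EIC 2. Interferon-stimulated genes, which are not specific to leukocytes, summed to 488 to 5785 CPM in EIC and to 1745 to 10139 CPM in 16IC. NK and cytotoxic genes summed to 1.96 to 25.3 CPM in EIC and to 7.21 to 48.5 CPM in 16IC, and MHC class II genes to 310 to 921 CPM and to 361 to 1538 CPM.

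A hypothesis, chosen and tested only after the data were seen, is that tumours with more Enpp1 may have a lower interferon score. Over the 10 tumours Pearson's r was -0.643 (permutation p = 0.0457, adjusted p = 0.236 over 6 relations) and Spearman's rho -0.515 (permutation p = 0.132, adjusted p = 0.407). Without EIC 2 and EIC 5, the tumours farthest from the median of Enpp1, r was -0.193, but leaving them out also narrows the range of Enpp1. Within EIC r was -0.672 and within 16IC -0.472 (n = 5 each), and with each genotype's mean removed -0.630. The other 5 relations, of Enpp1 or Nt5e with the interferon or MHC lists, had Pearson r from -0.561 to -0.035 and no permutation p under 0.05. These data do not decide the hypothesis.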
